A study of Mus musculus with 32 samples.

How the data were processed

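Liver RNA of 16 mice was measured by sequencing in 32 libraries. Each animal gave an input library, made with a stranded mRNA kit from bulk RNA, and an IP library, made with another kit from fragmented RNA pulled down with an antibody against m6A (the methylated adenosine of mRNA). The 16 animals fell into 4 groups of 4 by surgery (partial hepatectomy or sham) and genotype (Mettl14 knockout, here KO, or control animals with the floxed gene, here flox), which made 8 groups of 4 libraries. The labels give 1 age for each animal, from 71 to 77 days.

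Per the submitters' processing notes, reads were trimmed with fastp and aligned with STAR. The versions of both, the counting program, the annotation release, the strand setting and the genome build are not given in the sources used here. The deposited table holds estimated counts (expected counts in the unit's usual name), 1 column for each library and 55421 genes by Ensembl identifier, not scaled between libraries. Between 1.33% and 8.22% of the values of a column were not whole numbers, as when a read that fits several genes or places is split between them, so values of gene families with near-identical members are uncertain. All values were rounded to whole numbers. Genes were named by matching their positions to a table of RefSeq genes on GRCm38.p6, used only for names: 34622 genes received a symbol, among them 19619 of the 25532 genes with any count, which held 92.4% of all counts. The same matching after a shift of all positions by 1000000 bases named 585 genes.

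The total count was 8177784 to 12533931 in the input libraries and 7133766 to 24297854 in the IP libraries. A count of 0 was read with a floor of 3 counts, per library for single levels and over the group for fold changes, and intervals are at 95%. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fitted fold change of a gene at or near 0 in a group depends on the prior count of 2 and is no bound, so such genes are also given as a bound or ratio from the counts.

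Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter (minimum count 10), 1 coefficient for each group, quasi-likelihood F-tests and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. Input comparisons were fitted over the 16 input libraries (8769 genes), and comparisons of IP with input over all 32 libraries (14328 genes). A gene was called enriched or depleted in IP at an absolute log2 IP/input of at least 1. The difference in log2 IP/input between 2 groups is named IP/input below. The design, the alternatives, the rule for named genes and 39 gene lists (573 genes, of which 549 were found by name) were fixed before the data were examined. Comparisons within the 16 IP libraries alone (14020 genes), a filter at a mean of 50 CPM (counts scaled to a common library total) and a fit without the 2 sham flox animals aged 77 days were added after the data had been seen.

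Genes were named by a rule: Mettl14 and the fibrinogen genes Fga, Fgb and Fgg always, and for each comparison up to 10 genes each way with the largest log2 changes among those past the threshold, with a mean of at least 5 CPM in the higher group (input libraries for IP/input), a symbol that is not of a predicted model, and every replicate of one group above every replicate of the other (this last condition was not used for interactions). Of each list described, up to 4 members with the smallest p-values were named, with any member of the opposite direction past the threshold. Genes named outside this rule are marked as chosen after their values were seen. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), with its estimated correlation and with fry, and adjusted over the lists of 1 comparison. A p-value of a list is given with the preset correlation unless named otherwise.

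DESeq2 1.42.0 was run as the other tool. On simulated data with the spread of these libraries, DESeq2 called 386 unchanged genes of 8134 in an input comparison, 103 of 13298 in an IP comparison and 583 of 14118 in an IP/input comparison, where edgeR called 1, 1 and 0. In the same data edgeR recovered 4% of 16-fold changes in input, 42% in IP and 2% in IP/input, and at a low spread 100% in all 3. In the real input libraries DESeq2 called 1052 genes between hepatectomised KO and flox animals and 444 to 808 in the other drawn splits of the same 8 libraries (25 with the real one). For sham animals 5 of 25 splits gave at least the real 653 (highest other 854). Its counts are therefore given beside those of edgeR, not in their place.

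The labels pair the input and IP libraries of an animal. Over 184 abundant genes the correlation between both libraries of an animal, after removal of group means, was -0.2 to 0.37 (median 0.1, across genes, which are not independent replicates), and 10 of 16 inputs matched the IP library of their own animal best within the group. A fit with the animal as a block was an alternative. Its prior degrees of freedom were infinite, so each gene took the spread of the trend with abundance (for Fga 0.00366, against 0.0767 without blocks), and its p-values for abundant genes are too small. For 8 genes the log2 IP/input of each animal was therefore also compared between groups with an exact 2-sided permutation test, whose smallest possible p is 0.029 with 4 animals against 4. No pair of libraries was identical (highest correlation 0.921). The other alternatives were upper-quartile factors, library totals, TMM within each kind of library, no filter on low counts, a fold threshold, age as a covariate, the replicate number as a block, the 8 compared libraries alone and leaving out each animal in turn. Peaks and positions along transcripts were not analysed here. Results of some single genes are not reported here.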

Results

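The series asks what the m6A mark of mRNA, and the enzyme that writes it, do in the liver after part of it is removed, with fibrinogen genes as the centre of interest. METTL14 is the partner of METTL3 in the methyltransferase. Input and IP libraries were made from the livers of 4 sham flox, 4 sham KO, 4 hepatectomised flox and 4 hepatectomised KO mice. Library totals are given above.

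The IP libraries held more genes than the inputs of the same livers. An input library had 4171 to 9344 genes with at least 10 counts (median 5289), and an IP library 6669 to 16829 (median 11389). The IP library was higher in 16 of 16 animals, by 5586 genes on average (exact 2-sided permutation p = 3.05e-05, the smallest that 16 pairs can give). KO inputs had 1645 more such genes than flox inputs (8 against 8, exact permutation p = 0.0146), while KO and flox IP libraries differed by 782 (p = 0.508, exact permutation). The IP library of hepatectomised KO replicate 4 had the lowest total (7133766) and the fewest genes (6669). Among genes at a log2 CPM of 6 to 8 the median coefficient of variation within groups was 152% in input and 50% in IP libraries.

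**Figure D1:**
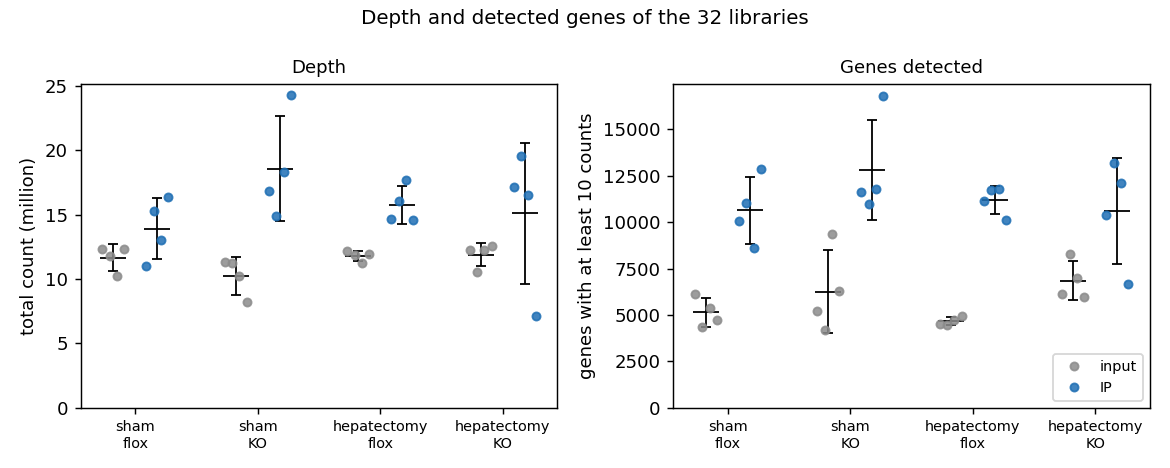
Total count (left) and number of genes with at least 10 counts (right) of each library, with group means and SD (n = 4), inputs in grey and IP libraries in blue. Inputs lie between 4171 and 9344 genes and IP libraries between 6669 and 16829.

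Mettl14 (ENSMUSG00000028114, protein-coding, chromosome 3, 123368297 to 123386108, minus strand; positions as the table gives them, genome build not given in the sources used here) could not be read well enough to check the genotypes. Its count was 0 in 16 of 16 input libraries, which allows up to 0.24 to 0.37 CPM per library. In the IP libraries 5 of 8 flox animals had counts of it (2.2 ± 3 CPM, mean and SD, highest count 124) and 3 of 8 KO animals (0.97 ± 1.4 CPM, highest count 60; exact 2-sided permutation p = 0.34). A difference between genotypes in Mettl14 was not detectable at this depth.

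Transferrin, the iron carrier of plasma, was the gene that edgeR called higher in KO inputs after both kinds of surgery, a call that depended on the scaling and the tool. Other splits of the same libraries gave up to 4 genes in sham and 5 in hepatectomised animals, so chance was not excluded for the counts of 1 and 3. Trf went from 7640 ± 1280 to 10800 ± 1530 CPM in sham animals (log2 change 0.51, SE 0.09, adjusted p = 0.0028, n = 4 each). It went from 9890 ± 708 to 13400 ± 1170 CPM in hepatectomised animals (0.44, SE 0.09, adjusted p = 0.02). The mitochondrial mRNA mt-Co1, which encodes a subunit of cytochrome oxidase, rose in hepatectomised KO livers from 7960 ± 543 to 13800 ± 3310 CPM (0.79, SE 0.12, adjusted p = 1.9e-05). The third gene past the threshold there was the unnamed ENSMUSG00000097971 (1.89, SE 0.23, adjusted p = 9.1e-08). Scd1, the main desaturase of fatty acids in liver, fell by 1.61 on the log2 scale from sham to hepatectomised KO animals (SE 0.28, adjusted p = 0.0023; 3410 ± 1610 to 1120 ± 441 CPM). Both were chosen after their values were seen.

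These 5 calls were all that edgeR made over the input comparisons: 1 gene higher in KO than flox sham animals, 3 higher in KO than flox hepatectomised animals, and 1 lower after hepatectomy in KO. The count was 0 for hepatectomy against sham in flox animals and for the interaction of genotype and surgery. At an unadjusted p under 0.05 the counts were 804, 1227, 242, 1488 and 1082 genes, where chance gives about 438, and DESeq2 called 653, 1052, 148, 1353 and 1240. Of these 59, 126, 86, 799 and 511 were lower. The median of all genes was higher in KO than flox inputs by 0.29 (sham) and 0.46 (hepatectomy) on the log2 scale. The change of Trf relative to the median gene was therefore 0.22 in sham and -0.02 in hepatectomised animals, and that of mt-Co1 0.33. With the 50 CPM filter the median moved by only 0.08 (sham) and 0.11 (hepatectomy), so these relative values depend on the genes taken. With upper-quartile factors the shift after hepatectomy was 0.26 and the 3 genes higher and 0 lower became 2 and 2. The Trf calls ended with upper-quartile factors, with DESeq2 and in fits of only the 8 libraries compared, and the Trf and mt-Co1 calls with the 50 CPM filter.

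Leaving out 1 input library raised many of these counts, and those not given here stayed within 1.5 times. KO against flox sham gave 12, 13, 17 and 12 genes without sham flox replicates 1 to 4, and 15, 2, 9 and 16 without sham KO replicates 1 to 4. KO against flox after hepatectomy gave 7 without flox replicate 3 and 9, 5 and 5 without KO replicates 2, 3 and 4. Hepatectomy against sham gave 5, 1 and 2 in flox animals without sham replicates 1, 2 and 3 and 3 without hepatectomy replicate 3. In KO animals it gave 5, 2, 5 and 5 without sham replicates 1 to 4 and 4, 2, 9 and 8 without hepatectomy replicates 1 to 4. The interaction gave 1 to 4 genes without each of the 16 libraries. Of the 35 lists tested in the inputs, 1 passed in 1 comparison: male-biased liver genes were lower in KO sham animals (median log2 change -1.43, adjusted p = 0.0015), with adjusted p = 0.57 with an estimated correlation. None of its members passed over all genes (0) or adjusted over the list alone (0).

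Fibrinogen mRNA was lower in the IP libraries of hepatectomised KO animals, while no change of it passed the threshold in their inputs. Fga, Fgb and Fgg encode the chains of fibrinogen, the clot-forming protein made by hepatocytes (Fga ENSMUSG00000028001, 83026076 to 83033627, plus strand; Fgb ENSMUSG00000033831, 83040141 to 83049863, minus strand; Fgg ENSMUSG00000033860, 83007724 to 83015049, plus strand; all protein-coding on chromosome 3). In hepatectomised animals the IP level of Fga fell from 58000 ± 14000 CPM in flox to 14600 ± 5270 in KO (log2 change -1.99, SE 0.34, adjusted p = 0.0017, n = 4 each). That of Fgb fell from 11200 ± 2860 to 3860 ± 945 (-1.53, SE 0.32, adjusted p = 0.0096). Fgg was 6120 ± 2140 in flox and 2430 ± 1480 in KO (-1.33, SE 0.39, adjusted p = 0.09). The inputs of the same animals held Fga at 47000 ± 5120 and 42900 ± 10700 CPM, Fgb at 10900 ± 918 and 10700 ± 2600 and Fgg at 6820 ± 683 and 6310 ± 1590. These were log2 changes of -0.13, -0.03 and -0.11 (adjusted p = 0.58, 1 and 1). Relative to the median gene, which moved by 0.46, they were -0.59, -0.49 and -0.57. With the 50 CPM filter the median gene moved by only 0.11. Whether the inputs of Fga, Fgb and Fgg fell thus depends on the scaling and the genes taken.

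In IP/input the genotype difference after hepatectomy was -1.98 for Fga (SE 0.28, adjusted p = 7.3e-06), -1.62 for Fgb (SE 0.27, adjusted p = 0.00018) and -1.34 for Fgg (SE 0.36, adjusted p = 0.05, not called). The median gene moved by -0.99 in this comparison, and relative to it the differences were -0.99, -0.63 and -0.35. With the 50 CPM filter the median gene moved by -0.24, so these relative values depend on the genes taken. Per animal, log2 IP/input of Fga was 0.43 ± 0.3 in flox and -1.55 ± 0.74 in KO (exact 2-sided permutation p = 0.029 for Fga, Fgb and Fgg alike, the smallest possible). In sham animals KO and flox differed in IP/input by -0.27, -0.28 and -0.46 for the 3 genes, none past the threshold. In IP they differed by 0.02, 0.14 and -0.04. The interaction of genotype and surgery did not pass: -1.71, -1.34 and -0.88 in IP/input (adjusted p = 0.054, 0.07 and 0.47) and -2.01, -1.67 and -1.29 in IP (adjusted p = 0.18, 0.28 and 0.59). A larger loss after hepatectomy than after sham surgery was therefore not shown by these fits, which do not pair the libraries of an animal. Per animal the KO minus flox difference in log2 IP/input was -1.98 after hepatectomy and -0.22 after sham surgery for Fga. It was -1.57 and -0.3 for Fgb and -1.41 and -0.54 for Fgg. The interaction was not tested per animal.

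None of the 3 fibrinogen genes was called enriched in the IP libraries of flox animals: log2 IP/input was -0.39, -0.29 and -0.51 in sham and 0.46, 0.19 and 0 in hepatectomised flox animals. In hepatectomised KO animals all 3 were depleted, at -1.52, -1.43 and -1.34 (adjusted p = 1.1e-06, 1.1e-06 and 0.0015). Relative to the median gene Fga, Fgb and Fgg lay below 0 in every group: -1.34, -1.24 and -1.46 in sham flox, -0.81, -1.08 and -1.27 in hepatectomised flox, -1.37, -1.28 and -1.68 in sham KO and -1.83, -1.74 and -1.65 in hepatectomised KO animals. With the 50 CPM filter the median gene itself stood at only 0.11, 0.16, 0 and -0.04 in these groups. How the 3 genes compare with others therefore depends on the genes taken. DESeq2 ended the IP/input calls of Fga and Fgb and the depletion call of Fgg. The 50 CPM filter ended the IP/input call of Fgb, and leaving out hepatectomised KO replicate 3 ended the depletion call of Fgg (-1.02, adjusted p = 0.11). In the fit with the animal as a block Fgg passed in IP/input after hepatectomy (-1.4, adjusted p = 5.9e-07). Fga passed between surgeries in flox (0.93, adjusted p = 2e-41) and KO animals (-0.82, adjusted p = 7.9e-31) and in the interaction (-1.75, adjusted p = 3.5e-74), and Fgb passed in KO animals (-0.77, adjusted p = 0.00092) and in the interaction (-1.28, adjusted p = 3.1e-05). That fit gave Fga a spread of 0.00366, and per animal the surgery difference of Fga had exact permutation p = 0.057 in flox and 0.057 in KO animals.

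**Figure D2:**
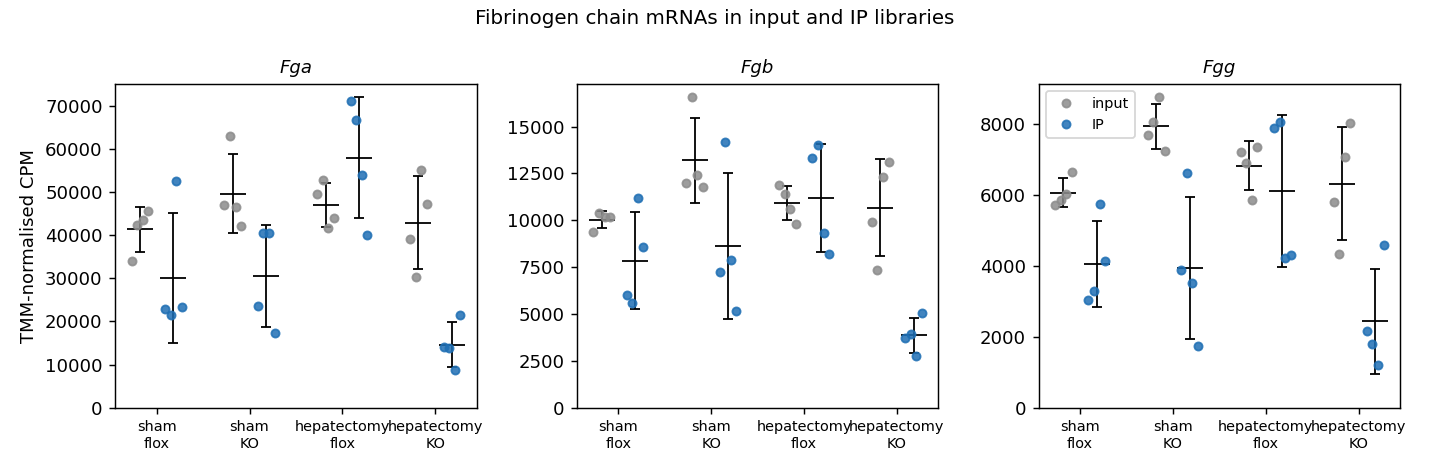
TMM-normalised CPM of Fga, Fgb and Fgg in each input (grey) and IP (blue) library by group, with mean and SD (n = 4). IP levels of Fga average 58000 in hepatectomised flox and 14600 in hepatectomised KO animals, while the inputs average 47000 and 42900.

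Which mRNAs were higher or lower in IP than in input was asked within each group. The 2 kinds of library were made with different kits, from bulk and from fragmented RNA. Enrichment or depletion here therefore cannot be assigned to the antibody alone. In sham flox livers Fabp1, the fatty acid binding protein of hepatocytes, was enriched (log2 IP/input 1.71, SE 0.34, adjusted p = 0.0077; 2780 ± 399 CPM in IP and 894 ± 105 in input, n = 4). So was Apoa5, an apolipoprotein that lowers plasma triglyceride (1.06). Btg2 (-3.46), the acute phase genes Lcn2 (-2.68, SE 0.47, adjusted p = 0.002) and Steap4 (-2.01), and Serpina3n (-1.23, SE 0.23, adjusted p = 0.0047, chosen after its values were seen) were depleted. In hepatectomised flox livers Mettl7b was the enriched gene the rule named (1.55, SE 0.38, adjusted p = 0.032). In sham KO livers Steap4 (-2.43), Serpina3n (-1.76, SE 0.24, adjusted p = 4.5e-06) and B3galt1 (-2.93) were depleted and edgeR called no gene enriched, where DESeq2 called 2035.

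In hepatectomised KO livers most genes that edgeR called were depleted, acute phase and secreted liver proteins among them, while DESeq2 called 1813 genes enriched and 227 depleted. Serpina1e, a protease inhibitor, had log2 IP/input of -4.33 (SE 0.42, adjusted p = 5.4e-11), and Saa2, an acute phase apolipoprotein, -4.62 (SE 0.8, adjusted p = 0.00026). Steap4 (-2.68, SE 0.4, adjusted p = 1.2e-05) and the major urinary proteins Mup11 (-4.66), Mup7 (-4.41) and Mup3 (-3.06) were also lower, and counts of Serpina1, Serpina3, Saa and Mup genes are uncertain because reads fitting several members could be split. Of 19 acute phase genes 9 fell, and 13 did adjusted over the list alone (median log2 -1.87, adjusted p = 8.4e-21, adjusted p = 0.017 with an estimated correlation), among them Hp at -1.92 and Saa4 at -2.09. Of 13 secreted liver proteins 4 fell, and 10 did adjusted over the list alone (median log2 -0.81, adjusted p = 8.9e-10, adjusted p = 0.018 with an estimated correlation): Alb -1.23, Apoa1 -0.91, Trf -0.98 and Ambp -1.38. Elovl3 (-11.67), Cyp8b1 (-7.34), Saa1 (-3.43) and Retreg1 (-2.87) were depleted too. The 3 enriched genes were Kansl3 (12.07), Ncl (nucleolin, 2.07, SE 0.48, adjusted p = 0.021) and Sned1 (12.73), named after their values were seen.

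The enriched and depleted counts were 33 and 4 in sham flox, 174 and 0 in hepatectomised flox, 0 and 3 in sham KO and 3 and 44 in hepatectomised KO animals. At an unadjusted p under 0.05 they were 4340, 5003, 2935 and 2851 in total, and DESeq2 called 3537, 4127, 2075 and 2040. The DESeq2 calls were 3384 enriched and 153 depleted in sham flox, 4044 and 83 in hepatectomised flox, 2035 and 40 in sham KO and 1813 and 227 in hepatectomised KO, so the balance in KO animals depended on the tool. The median gene stood at 0.95, 1.27, 0.71 and 0.31 on the log2 scale, and relative to it Fabp1 was at 0.76 and Mettl7b at 0.28. With the 50 CPM filter the median gene stood at 0.11, 0.16, 0 and -0.04. Without TMM factors the split was 24 and 9 in sham flox, 83 and 2 in hepatectomised flox and 7 and 34 in hepatectomised KO. With the 50 CPM filter it was 10 and 10 in sham flox, 11 and 0 in hepatectomised flox, 0 and 5 in sham KO and 14 and 63 in hepatectomised KO. Most of the 174 calls in hepatectomised flox animals were thus not made with that filter. The inputs of that group held the fewest genes with at least 10 counts (mean 4662). How many of the 174 genes were missing from those inputs was not tested. Of the 174 genes 173 had a log2 IP/input of at least 2. With the animal as a block the split was 25 and 13, 67 and 2, 1 and 15 and 0 and 51 in the 4 groups, Btg2 (adjusted p = 0.17) and Retreg1 (0.3) no longer passed, and Fgg was depleted in sham KO (-1.1, adjusted p = 1.2e-08).

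Leaving out sham flox replicates 2, 3 and 4 gave 9, 12 and 10 genes. Leaving out hepatectomised flox replicates 1 to 4 gave 59, 74, 82 and 57, sham KO replicates 2 and 3 gave 7 and 6, and hepatectomised KO replicates 1 and 3 gave 27 and 20. In sham flox animals the call of Fabp1 ended without replicate 3 (1.64, adjusted p = 0.073) or 4 (1.76, 0.052), that of Apoa5 without replicate 2, 3 or 4 (adjusted p = 0.097, 0.12 and 0.15). There that of Steap4 ended without replicate 2 or 4 (0.083 and 0.06) and that of Btg2 without any of the 4 (0.063 to 0.15). In hepatectomised flox animals that of Mettl7b ended without replicate 1, 3 or 4 (0.11, 0.13 and 0.09). In sham KO animals that of B3galt1 ended without replicate 1, 3 or 4 (0.17, 0.17 and 0.27). In hepatectomised KO animals Mup11 (-3.56, adjusted p = 0.18), Saa1 (-2.96, 0.11) and Saa4 (-1.59, 0.19) were lost without replicate 3. Saa4 was lost without replicate 1 (0.087), Ambp without replicate 1, 3 or 4 (0.3, 0.31 and 0.074), Mup7 without replicate 1, 2 or 4 (0.17, 0.13 and 0.28) and Retreg1 without any of the 4 (0.11 to 0.3).

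Whether IP/input differed between genotypes was tested next. After hepatectomy it fell in KO animals for Cyp2e1, the ethanol-oxidising cytochrome of pericentral hepatocytes (-2.51, SE 0.43, adjusted p = 0.00034, relative to the median gene -1.52). It also fell for the acute phase genes Hp (haptoglobin, -2.29, SE 0.39, adjusted p = 0.00034, relative -1.3), Saa2 (-4.99), Saa4 (-2.83) and Steap4 (-2.16). Per animal log2 IP/input of Cyp2e1 was 0.45 ± 0.47 in flox and -2.36 ± 1.32 in KO, and that of Hp 0.29 ± 0.64 and -2.15 ± 1.14 (exact permutation p = 0.029 for each). Hnf4a, a master regulator of hepatocyte genes, was at -2.13 (adjusted p = 0.04). The 10 genes with the largest changes were Sec22c, Plag1, Bbs10, LTO1, Mppe1, Slc22a7, Sdf4, Rhbdd2, Mief1 and Selenoi (-21.64 to -13.94). Such fitted values rest on libraries at or near 0 and are no measure of size. In sham animals 3 genes fell: Zfp62 (-12.38), Eef1d (-13.15, chosen after its values were seen) and Serpina3k (-1.35, SE 0.27, adjusted p = 0.031), a member of a serpin family whose reads could be split.

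The count after hepatectomy was 1 gene higher (ENSMUSG00000098178, 3.12, named after its value was seen) and 101 lower, and in sham animals 0 higher and 3 lower. After hepatectomy the flox inputs held 4460 to 4948 genes with at least 10 counts and the KO inputs 5972 to 8273. A gene present in KO inputs and missing from flox inputs has a lower IP/input in KO animals without any change in IP. How many of the 101 were of this kind was not tested. At an unadjusted p under 0.05 there were 3063 and 2120, and DESeq2 called 3231 and 2483, of which 618 and 641 were higher. The median gene moved by -0.99 and -0.24 (-0.24 and -0.13 with the 50 CPM filter). With library totals in place of TMM factors the count after hepatectomy was 2 and 35. Of 19 acute phase genes 5 fell, 9 adjusted over the list alone (median -1.93, adjusted p = 0.0067, adjusted p = 0.57 with an estimated correlation). Of 14 hepatocyte transcription factors 1 fell, 2 adjusted over the list alone (median -1.88, adjusted p = 0.013, adjusted p = 0.38 with an estimated correlation), with Cebpa at -2.18, Ppara at -2.47 and Onecut1 at -3.53. Of 15 xenobiotic cytochromes P450 1 fell, 6 adjusted over the list alone (median -1.86, adjusted p = 0.02, adjusted p = 0.38 with an estimated correlation), with Cyp2c37 at -7.43, Cyp1a2 at -1.98 and Cyp2c29 at -2.2. With the animal as a block the counts were 48 after hepatectomy and 12 in sham animals. The calls of Steap4 (adjusted p = 0.13), Hnf4a (0.11), Sec22c (0.4), Plag1 (0.58), Bbs10 (0.29), LTO1 (0.31), Mppe1 (0.65), Slc22a7 (0.73), Rhbdd2 (0.25) and Mief1 (0.23) ended.

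Without hepatectomised flox replicates 1, 2 and 4 the count was 54, 65 and 57, and without KO replicates 1 to 4 it was 27, 38, 21 and 41. In sham animals it was 5 and 6 without flox replicates 1 and 4 and 1 without KO replicate 2 or 3, each of which also ended the call of Zfp62 (adjusted p = 0.064 and 0.098). Leaving out any 1 of the 8 animals ended the calls of Sec22c, Plag1, Bbs10, LTO1, Mppe1, Slc22a7, Rhbdd2 and Mief1 (adjusted p from 0.057 to 0.2). KO replicate 3 ended that of Saa4 (-2.35, 0.086), flox replicates 1 and 2 and KO replicates 1 to 4 that of Steap4 (0.053 to 0.16), and flox replicates 1, 2 and 4 and KO replicates 1, 3 and 4 that of Hnf4a (0.1 to 0.16).

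Few genes passed between surgeries in IP/input, and other splits of the animals gave up to 36 genes in flox and 7 in KO animals, so chance was not excluded. A low count does not show that few genes changed, since edgeR recovered 2% of 16-fold changes of IP/input in simulated data. In flox animals Serpina3n, an acute phase protease inhibitor, rose by 1.57 after hepatectomy (SE 0.32, adjusted p = 0.02). Its IP level went from 2550 ± 1730 to 7970 ± 1920 CPM, and its inputs were at 6300 ± 1080 and 7040 ± 597. Per animal the exact permutation p was 0.029. The rule that named Serpina3n required the animals of both groups to be fully separated in log2 IP/input. That fixes this p at its smallest value, so it adds no support. The other genes the rule named were Nifk, Adora1, Golga5, Atp11a, Metap2, Lactb and Naa60 (10.09 to 14.93) and Tent4a, Eef1d and Naip2 (-12.98 to -13.43), fitted values that rest on libraries at or near 0. In KO animals Serpina1e (-3.33, SE 0.53, adjusted p = 0.00047), Cyp2e1 (-2.07, SE 0.43, adjusted p = 0.029), Cyp8b1 (-7.19), Elovl3 (-10.52) and the predicted gene Gm8893 (-3.81, chosen after its values were seen) fell. Among the 6 genes with an interaction were Serpina1e (-3.42, SE 0.73, adjusted p = 0.041), Nifk, Sdf4, Metap2 and Commd1.

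The counts were 19 higher and 7 lower in flox, 0 and 5 in KO, and 1 and 5 for the interaction, against 2925, 1704 and 2057 at an unadjusted p under 0.05 and 3349, 1611 and 3190 by DESeq2, of which 1966, 719 and 1299 were higher. Without the 2 animals aged 77 days the count in flox was 1 higher and 2 lower. The median gene moved by 0.22, -0.45 and -0.85. With the animal as a block the totals were 5, 25 and 15. That fit ended the calls of Nifk (adjusted p = 0.15), Adora1 (0.89), Golga5 (0.59), Atp11a (0.26), Metap2 (0.11), Lactb (0.17), Naa60 (0.26), Tent4a (0.46), Eef1d (0.1) and Naip2 (0.72). In the interaction it ended those of Commd1 (1), Nifk (0.22), Sdf4 (0.18) and Metap2 (0.19).

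Leaving out sham flox replicates 1 to 4 gave 10, 8, 12 and 10 genes between surgeries in flox animals and hepatectomised flox replicate 1 gave 14. Without sham flox replicate 2 Serpina3n was at 1.23 (adjusted p = 0.12). The calls of Nifk, Adora1, Golga5, Atp11a, Lactb, Naa60, Tent4a and Naip2 ended without several of the 8 animals (0.053 to 0.14). In the interaction those of Commd1, Nifk and Metap2 ended without most of the 16 (0.053 to 0.13). In KO animals sham replicates 1 and 2 gave 2 and 3 and hepatectomy replicates 1 to 4 gave 3, 8, 2 and 14. The call of Cyp2e1 ended without sham KO replicate 1, 2 or 4 (adjusted p = 0.18, 0.25 and 0.076) or hepatectomised KO replicate 1 or 3 (0.12 and 0.42). That of Elovl3 ended without sham KO replicate 1 (0.07) or hepatectomised KO replicate 1 or 3 (0.12 and 0.072). The interaction count was 35 without sham KO replicate 3, 11 without hepatectomised KO replicate 4, and 3 without sham KO replicate 4. It was 2 without sham flox replicate 2 or 4, sham KO replicate 1 or hepatectomised KO replicate 3, and 1 without sham KO replicate 2 or hepatectomised flox replicate 1 or 2. The interaction of Serpina1e ended without 8 of the 16 animals, at adjusted p from 0.052 to 0.13: sham flox replicates 2 and 4, sham KO replicate 2, hepatectomised flox replicates 1, 2 and 4 and hepatectomised KO replicates 2 and 3.

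Group differences within the IP libraries combine mRNA level and methylation. In sham animals some mRNAs known for higher expression in males were lower in the IP libraries of KO livers. Hsd3b5, a steroid-metabolising enzyme, fell from 277 ± 118 to 0.29 ± 0.493 CPM (log2 change -9.88, SE 1.12, adjusted p = 3.8e-05, n = 4 each). The inputs held Hsd3b5 at 34 ± 47.6 and 6.22 ± 11.4 CPM (-2.45, adjusted p = 1), so a loss of the mRNA from the liver was not shown. In the same animals 5 major urinary protein genes fell by 2.73 (Mup3) to 7.9 (Mup17) on the log2 scale, with Mup11, Mup7 and Mup16 between, while the inputs of Mup11 were at 571 ± 340 and 201 ± 103 and those of Mup17 at 204 ± 126 and 42.1 ± 45.8 CPM. Glul, glutamine synthetase of the hepatocytes around the central vein, fell from 1300 ± 340 to 311 ± 86.8 CPM (-2.06, SE 0.3, adjusted p = 0.00097). Gstm3, a glutathione transferase, rose from 34 ± 4.38 to 477 ± 406 CPM (3.81, SE 0.54, adjusted p = 7e-04), as did Aldh1b1, a mitochondrial aldehyde dehydrogenase (2.44, SE 0.37, adjusted p = 0.0017). Btg2 (3.3, adjusted p = 0.045) and Top2a, the topoisomerase of dividing cells, rose too (1 count in the 4 sham flox libraries, ratio 443, counting interval 79.6 to 17500; adjusted p = 0.049). Ly6d, listed at 0 in sham flox and at 55.7 ± 78.5 CPM in sham KO animals, and the unnamed ENSMUSG00000074373 (7.29) were chosen after their values were seen.

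Of 10 male-biased genes 1 fell, and 3 did adjusted over the list alone (median -1.09, adjusted p = 4e-16, adjusted p = 0.0018 with an estimated correlation); Slco1a1 was at -3.93, Elovl3 at -1.77 and Cyp7b1 at -2.24. Of 14 pericentral genes 1 fell, and 2 did adjusted over the list alone (median -0.66, adjusted p = 6.9e-06, adjusted p = 0.024 with an estimated correlation); Slc1a2 was at -1.68, Cyp2e1 at -0.98 and Oat at -0.94. These 2 of 38 lists held with an estimated correlation, of 18 that passed. Stellate cell and fibroblast markers were higher (15 tested, median 1.53, adjusted p = 1.2e-08, adjusted p = 0.053 with an estimated correlation). Of them 0 passed over all genes and 2 adjusted over the list alone; Col3a1 was at 4.84, Col1a2 at 1.79, Ngfr at 2.56 and Lrat at 1.53. Immediate early genes had a median of 1.75 (11 tested, adjusted p = 7.1e-06, adjusted p = 0.15 with an estimated correlation; 1 past over all genes, 5 adjusted over the list alone), with Egr1 at 2.9, Ier2 at 1.51 and Fos at 3.86. Cell cycle genes had a median of 3.51, or 3.4 with members at 0 set to their bound (28 tested, adjusted p = 0.00049, adjusted p = 0.21 with an estimated correlation; 1 past over all genes, 2 adjusted over the list alone), with Ccnd1 at 4.15. Monocyte and neutrophil markers had a median of 4.54, or 3.11 at the bound (8 tested, adjusted p = 0.014, adjusted p = 0.14 with an estimated correlation, 0 past over all genes, 4 adjusted over the list alone), with Retnlg, S100a8, Itgam and Ccl2 the members with the smallest p-values. Of the 28 cell cycle genes 10 were at 0 in a group, and of these 8 markers 4 were. The cell cycle gene Aurka, at 6.9, was at 0 without sham KO replicate 4, the IP library with the most genes (16829). Neither list was tested without that library.

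In total 6 genes were higher and 7 lower in KO sham animals (798 at an unadjusted p under 0.05, 701 given by chance), and the median gene moved by 0.16. DESeq2 called 163 higher and 23 lower. The count was 2 higher and 6 lower with age as a covariate, 1 higher and 7 lower without the 2 animals aged 77 days, 9 higher and 5 lower with the 50 CPM filter, and 4 higher and 13 lower with only the 8 libraries compared. It was 8 without sham flox replicate 3, 7 without sham KO replicate 1 or 2 and 8 without sham KO replicate 4. Top2a lost its call without any 1 of the 8 libraries (adjusted p from 0.064 to 0.23), Btg2 without sham flox replicate 1, 2 or 3 (0.17, 0.16 and 0.2) or sham KO replicate 1 or 2 (0.06 and 0.29). Mup11 and Mup16 lost theirs without sham flox replicate 3 (0.1 and 0.38) or any 1 of the 4 sham KO libraries (0.062 to 0.11), and Mup7 without sham flox replicate 1 or 3 (0.064 and 0.16) or any 1 of the 4 sham KO libraries (0.052 to 0.22). Mup3 lost its call without sham KO replicate 1 (0.053). Hsd3b5, Mup17, Glul, Gstm3 and Aldh1b1 passed without each of the 8 libraries in turn.

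After hepatectomy single enzymes of fatty acid, bile acid and thyroid hormone metabolism fell in the IP libraries of KO livers. Elovl3, which elongates very long fatty acids, was at 117 ± 53.4 CPM in flox and 0.0592 ± 0.0519 in KO animals (3 counts, ratio 2600, counting interval 890 to 12600; adjusted p = 4.4e-07). Its input level was 153 ± 113 and 207 ± 179. Cyp8b1, the sterol hydroxylase that makes cholic acid, fell from 290 ± 63.2 to 0.835 ± 1.63 CPM (-8.31, SE 1.05, adjusted p = 6.9e-05; inputs 302 ± 82.7 and 142 ± 86). Dio1, the deiodinase that activates thyroid hormone, fell from 91.1 ± 40 to 0.757 ± 1.36 CPM (-6.83; inputs 28.9 ± 52.9 and 52.7 ± 68.5), and Hsd3b5 fell from 79.3 ± 93.5 to 0.0225 ± 0.045 CPM (2 counts, ratio 2650, counting interval 732 to 21800). Nxpe2 (-7.22), Mup16 (-6.9), Mup17 (-6.45), Mup12 (-6.57), Mup9 (2 counts, ratio 257, counting interval 71.2 to 2120) and Bbs10 (0 counts in KO, at least 608-fold lower) fell too. Gstm3 rose from 121 ± 61.4 to 1170 ± 440 CPM (3.28, SE 0.52, adjusted p = 0.00074) and Ly6d, a surface protein of the Ly6 family, from 1.97 ± 1.47 to 304 ± 146 CPM (7.26). The translation genes Rps7 (3.05) and Rack1 (2.94) and the chaperonin subunit Cct2 (3.11) rose. So did Traf7 (8.44), Apip (6.02), Rap1gap2 and Slc51b (0 counts in flox, at least 895-fold and 670-fold higher).

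The 26 ribosomal protein mRNAs tested were all higher in KO animals: 9 passed over all genes and 25 adjusted over the list alone (median 1.59, adjusted p = 1.1e-23, adjusted p = 0.015 with an estimated correlation). Among them were Rps19 at 2.68 and Rpl6 at 1.91, though reads could be split with ribosomal pseudogenes. Of 10 male-biased genes 5 fell, 5 adjusted over the list alone (median -3.05, adjusted p = 1.1e-15, adjusted p = 0.0048 with an estimated correlation), including Serpina1e (-4.65) and Cyp7b1 (-5.11). Of 15 xenobiotic cytochromes P450 7 fell and 1 rose, 12 and 1 adjusted over the list alone (median -1.93, adjusted p = 4.9e-13, adjusted p = 0.012 with an estimated correlation). Cyp2e1 fell from 2260 ± 494 to 413 ± 331 CPM, Cyp2c29 (-2.88), Cyp3a13 (-2.29) and Cyp2f2 (-2.03) fell, and Cyp2a5 rose (1.82). Of 14 hepatocyte transcription factors 5 fell, 13 adjusted over the list alone (median -1.4, adjusted p = 9.5e-12, adjusted p = 0.0048 with an estimated correlation): Ppara, the fatty acid sensor (-2.66), Cebpa (-2.14), Hnf4a (-1.29) and Prox1 (-1.51).

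Most lists of other liver functions were lower, and targets of Nrf2 were higher. Of 20 coagulation factors 5 fell, 11 adjusted over the list alone (median -1.06, adjusted p = 4.5e-10, adjusted p = 0.03 with an estimated correlation), among them F10 (-1.56), F7 (-3.93), Hrg (-1.6) and Kng1 (-1.15). Of the 3 fibrinogen chains 2 fell, 3 adjusted over the list alone (median -1.53, adjusted p = 1.9e-05, adjusted p = 0.064 with an estimated correlation). Of 15 bile acid genes 5 fell and 0 rose, 7 and 1 adjusted over the list alone (median -1.32, adjusted p = 4.2e-07, adjusted p = 0.012 with an estimated correlation), with the uptake carriers Slco1b2 (-2.67) and Slc10a1 (-2.17). Of 9 gluconeogenesis genes 2 fell, 5 adjusted over the list alone (median -1.59, adjusted p = 2e-06, adjusted p = 0.038 with an estimated correlation): G6pc (-2.36) and Pck1 (-1.59), with Slc2a2 at -1.68. Of 19 acute phase genes 6 fell, 10 adjusted over the list alone (median -1.59, adjusted p = 1.2e-09, adjusted p = 0.16 with an estimated correlation): Saa4 (-3.16), Steap4 (-2.26), Saa1 (-4.33) and Hp (-2.15). Of 12 targets of Nrf2 1 rose, 3 adjusted over the list alone (median 0.93, adjusted p = 2e-06, adjusted p = 0.012 with an estimated correlation), with Gsta2 at 5.38, Txnrd1 at 1.28 and Gstm1 at 0.59. In the same libraries stellate cell markers had a median of 0.96, macrophage markers 0.58, sinusoidal endothelium 0.41 and cell cycle genes 1.05.

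KO against flox after hepatectomy gave 48 genes higher and 162 lower in IP (1866 at an unadjusted p under 0.05; DESeq2 363 higher and 446 lower; the median gene moved by 0.006), and 22 of 38 lists passed, 9 with an estimated correlation. Mitochondrial genes took 18.8, 16.4, 24.1 and 8.6% of the counts in hepatectomised KO IP replicates 1 to 4 and 10.3 to 12.7% in flox IP libraries, against 10.1 to 12.4% in the inputs of both. The composition of the IP libraries thus differed with the group, and what this does to the counts of genes was not tested. The count was 126 with only the 8 libraries compared, 430 without the filter on low counts and 377 (168 higher, 209 lower) with the 50 CPM filter. Without hepatectomised flox replicates 1, 3 and 4 it was 139, 116 and 121, and without KO replicates 3 and 4 it was 116 and 457, the last being the library with the lowest total. Elovl3, Hsd3b5, Cyp8b1, Dio1, Gstm3, Ly6d, Fga and Fgb passed without each of the 8 libraries in turn. Leaving out KO replicate 3 ended the calls of Rps19 (adjusted p = 0.074), Rpl6 (0.078), Rack1 (0.054), Hnf4a (0.053), Prox1 (0.07), Hrg (0.062), Kng1 (0.059) and Pck1 (0.08). Flox replicates 3 or 4 ended those of Rps7 (0.06 and 0.058), Rack1 (0.062 and 0.067), Cct2 (0.071 and 0.067), Rpl6 (0.1 and 0.11) and Pck1 (0.095 and 0.078). Other single libraries ended the calls of Rpl6 (flox replicate 2 and KO replicate 1, 0.08 and 0.056), Cct2 (KO replicate 4, 0.055), Hnf4a (flox replicate 3, 0.052), Prox1 (flox replicate 1 and KO replicate 1, 0.072 and 0.065), Hrg (KO replicates 1 and 2, 0.084 and 0.056). The same was so for Kng1 (flox replicates 1, 2 and 4 and KO replicate 1, 0.051 to 0.087), Slc10a1 (flox replicates 1 and 4 and KO replicates 1 and 2, 0.069 to 0.082) and Steap4 (flox replicate 2, 0.061), and for Mup9 (flox replicate 4 and KO replicates 1 and 2, 0.078 to 0.095), Mup12 (flox replicate 3 and KO replicate 1, 0.056 and 0.055) and Bbs10 (flox replicates 1 and 4 and KO replicates 1, 2 and 3, 0.06 to 0.097). The calls of Rap1gap2, Slc51b, Traf7, Apip and Cyp2a5 ended without most of the 8 libraries (adjusted p up to 0.27).

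**Figure D3:**
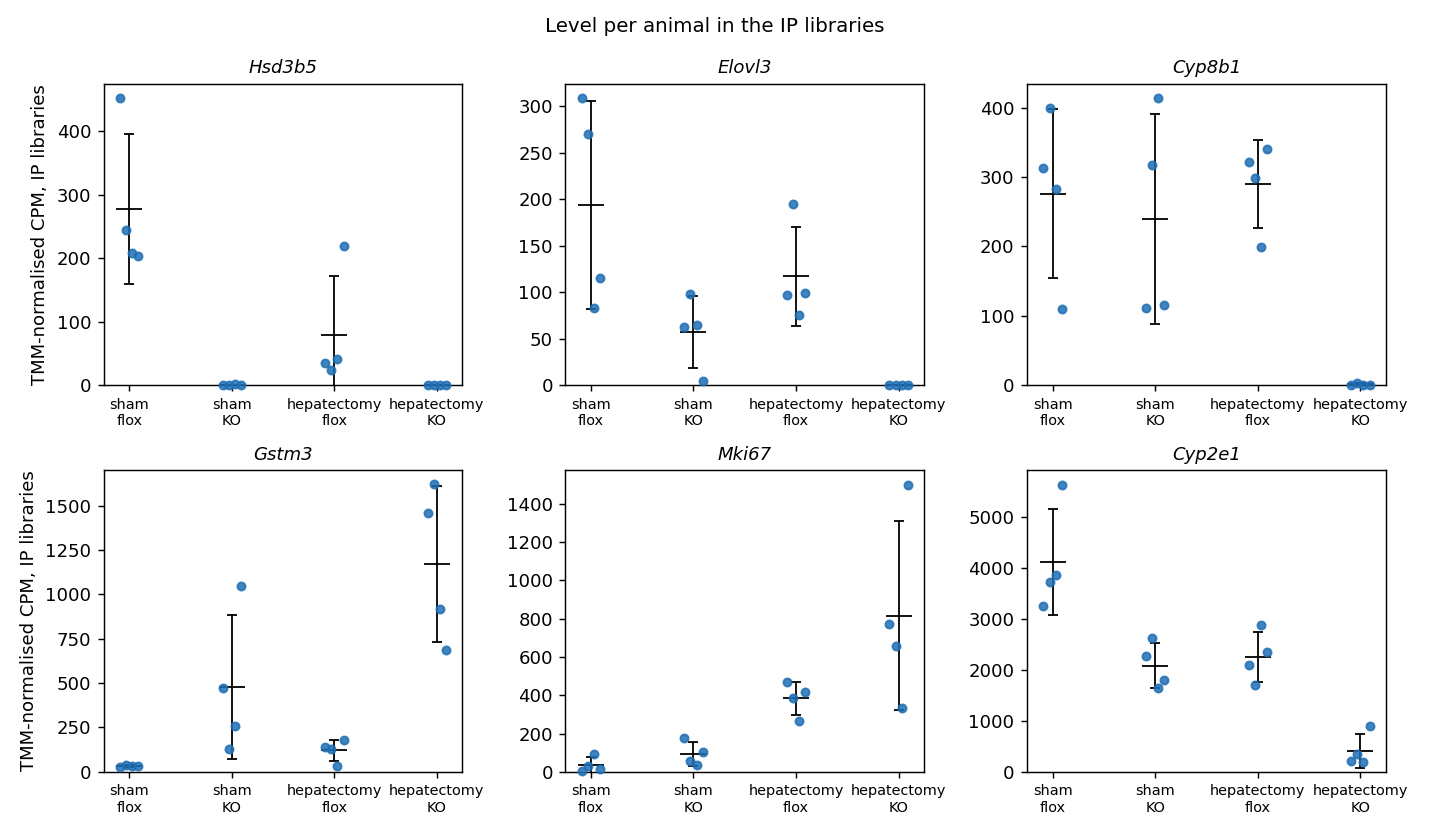
TMM-normalised CPM of 6 genes in the 16 IP libraries by group, points being animals and bars mean and SD (n = 4). Elovl3 and Cyp8b1 average 117 and 290 in hepatectomised flox and 0.0592 and 0.835 in hepatectomised KO animals, while Cyp2e1 averages 2260 and 413.

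After hepatectomy a few proliferation genes were higher in the IP libraries. In flox animals 16 of 38 lists passed, 0 with an estimated correlation and 0 by fry. In flox animals Top2a went from 1 count in the 4 sham libraries to 19.7 ± 8.34 CPM (ratio 1040, counting interval 187 to 41200; adjusted p = 0.042). The spindle gene Ckap2l rose by 7.92 (SE 1.45, adjusted p = 0.042) and Eppk1, a cytoskeletal linker of epithelia, rose from 366 ± 40.5 to 1240 ± 325 CPM (1.76, SE 0.3, adjusted p = 0.034). Mki67, the proliferation marker, was at 35.1 ± 40.7 in sham and 384 ± 87.3 CPM in hepatectomised flox animals (3.45, adjusted p = 0.064), while the inputs held it at 241 ± 177 and 235 ± 130. The fourth gene past the threshold was ENSMUSG00000074373 (9, named after its value was seen). Cell cycle genes had a median of 3.87, or 3.42 with members at 0 set to their bound (28 tested, adjusted p = 7.2e-11, adjusted p = 0.17 with an estimated correlation; 1 past over all genes, 12 adjusted over the list alone), with Foxm1 and Ccnd1 (3.39) among the smallest p-values.

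Acute phase genes had a median of 1.18 in hepatectomised flox animals (19 tested, adjusted p = 4.2e-10, adjusted p = 0.27 with an estimated correlation; 0 past over all genes, 3 adjusted over the list alone), with Lcn2 at 2.73, Steap4 at 1.76, Apcs at 1.8 and Hp at 1.1. Most of this rise rests on the 2 sham animals aged 77 days: the mean log2 level of the list rose by 1.39 against all 4 sham flox libraries and by 0.42 against the younger 2. Immediate early genes had a median of 1.82 (11 tested, adjusted p = 1.1e-07, adjusted p = 0.17 with an estimated correlation; 0 past over all genes, 5 adjusted over the list alone), with Btg2 at 3.43, Egr1 at 3.35, Ier2 at 1.93 and Jun at 2.46. Fatty acid synthesis genes had a median of -0.85 (11 tested, adjusted p = 1e-04, adjusted p = 0.17 with an estimated correlation; 0 past over all genes, 0 adjusted over the list alone), with Acly at -1.75, Me1 at -3.03, Scd1 at -1.14 and Srebf1 at -1.5. The count was 4 genes higher and 0 lower (972 at an unadjusted p under 0.05; DESeq2 274, of which 92 were lower). It was 1 with only the 8 libraries compared and 0 with age as a covariate or without the 2 sham animals aged 77 days. It was 0 without sham flox replicate 1 or 2 (the animals aged 77 days) or hepatectomised flox replicate 1, 2 or 3, 7 without sham flox replicate 3 and 8 without sham flox replicate 4. The calls of Top2a, Ckap2l and Eppk1 ended without the first 5 of these (adjusted p from 0.054 to 0.18). That of Top2a also ended without sham flox replicate 3 or 4 (0.075 and 0.062) and that of Ckap2l without replicate 3 (0.06).

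In KO animals hepatectomy raised Mki67 from 93.3 ± 61.5 to 817 ± 494 CPM in IP (3.13, SE 0.69, adjusted p = 0.03), with inputs at 320 ± 124 and 316 ± 88.1, and Rpl17 (2.03), Calu (1.83) and Atpif1 (2.05). The enzymes named above fell: Elovl3 from 57.1 ± 38.8 CPM to 3 counts (ratio 1270, counting interval 434 to 6160), Cyp8b1 (-8.04) and Dio1 (-5.14) on the log2 scale. So did the carboxylesterases Ces3b (-5.89) and Ces1d (-4.2), Npr2 (-5.85), Slc3a1, an amino acid transporter subunit (-4.61), Mup16 (-4.59), Upp2 (-3.74) and Saa1 (-3.63). Of 15 cytochromes P450 7 fell, 12 adjusted over the list alone (median -1.96, adjusted p = 4.7e-16, adjusted p = 0.018 with an estimated correlation), such as Cyp2e1 (-2.34), Cyp2f2 (-2.27), Cyp2c29 (-2.57) and Cyp3a13 (-1.92). Of 20 coagulation factors 4 fell, 12 adjusted over the list alone (median -0.97, adjusted p = 4.4e-09, adjusted p = 0.049 with an estimated correlation): Vtn (-1.67), Kng1 (-1.24), F7 (-3.61) and Plg (-1.36). Of 16 urea cycle and amino acid genes 4 fell, 11 adjusted over the list alone (median -1.5, adjusted p = 1.2e-07, adjusted p = 0.11 with an estimated correlation), among them Hpd (-1.62), Tdo2 (-2.11) and Hal (-1.97). Ribosomal protein genes had a median of 1 (26 tested, adjusted p = 1.1e-13, adjusted p = 0.049 with an estimated correlation; 0 past over all genes, 7 adjusted over the list alone), with Rps6 at 1.55, Rpl5 at 1.55 and Rps19 at 1.47. Cell cycle genes had a median of 2.26 (28 tested, adjusted p = 1.2e-07, adjusted p = 0.049 with an estimated correlation; 1 past over all genes, 1 adjusted over the list alone).

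In KO animals 7 genes were higher and 82 lower after hepatectomy (1326 at an unadjusted p under 0.05; DESeq2 83 higher and 331 lower), and 24 of 38 lists passed, 11 with an estimated correlation. The count was 9 with only the 8 libraries compared, 278 without the filter on low counts and 228 (73 higher, 155 lower) with the 50 CPM filter. Without sham KO replicates 2 and 3 it was 37 and 56, and without hepatectomised KO replicates 1 to 4 it was 49, 134, 35 and 253. Leaving out sham KO replicate 2 ended the calls of Mki67 (2.95, adjusted p = 0.14), Rpl17 (0.063), Calu (0.21), Npr2 (0.084), Ces1d (0.18), Saa1 (0.17), Cyp3a13 (0.061), Vtn (0.084), Kng1 (0.15), F7 (0.14), Plg (0.19), Tdo2 (-1.2, 0.4) and Hal (0.18). Hepatectomised KO replicate 1 or 3 ended those of Npr2, Ces1d, Saa1, Calu, Kng1, Plg, Hpd, Tdo2 and Hal (0.05 to 0.17). Of the same genes, Mki67, Rpl17, Calu, Ces1d, Saa1, F7, Plg, Hal, Cyp3a13 and Vtn lost their calls without at least 1 further library (0.052 to 0.14).

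A difference between genotypes in the response to surgery was tested in IP by the interaction. It passed for 4 genes, all with a lower response in KO animals: Elovl3 (-9.28, SE 1.12, adjusted p = 0.00013), Cyp8b1 (-8.11, SE 1.22, adjusted p = 0.0022), Slc3a1 (-5.54, SE 0.97, adjusted p = 0.017) and the predicted gene Gm8893 (-4.12, SE 0.61, adjusted p = 0.0022, chosen after its values were seen). At an unadjusted p under 0.05 there were 1105 genes, and DESeq2 called 90 higher and 178 lower. Acute phase genes differed by a median of -1.89 (19 tested, adjusted p = 3e-12, adjusted p = 0.21 with an estimated correlation; 0 past over all genes, 12 adjusted over the list alone), with Saa1 at -5.19, Saa2 at -5.51, Steap4 at -2.14 and Hp at -2.1. In mean log2 levels this interaction was -2.42 with all 4 sham flox libraries and -1.45 without the 2 animals aged 77 days, whose acute phase levels were low. Ribosomal protein genes differed by 1.33 (26 tested, adjusted p = 8.4e-16, adjusted p = 0.17 with an estimated correlation; 0 past over all genes, 4 adjusted over the list alone), with Rps6 at 1.82 and Rpl8 at 2.21. Coagulation factors differed by -1.16 (20 tested, adjusted p = 1.9e-06, adjusted p = 0.21 with an estimated correlation; 0 past over all genes, 6 adjusted over the list alone), with F7 at -4.08, Kng1 at -1.22, Vtn at -1.49 and Cpb2 at -2.1. The count was 10 without sham flox replicate 4, 7 without sham KO replicate 1, 12 and 39 without hepatectomised KO replicates 2 and 4 and 2 without both animals aged 77 days. The call of Slc3a1 ended without sham flox replicate 1 (adjusted p = 0.067) or 2 (0.052) or sham KO replicate 2 (0.085).

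**Figure D4:**
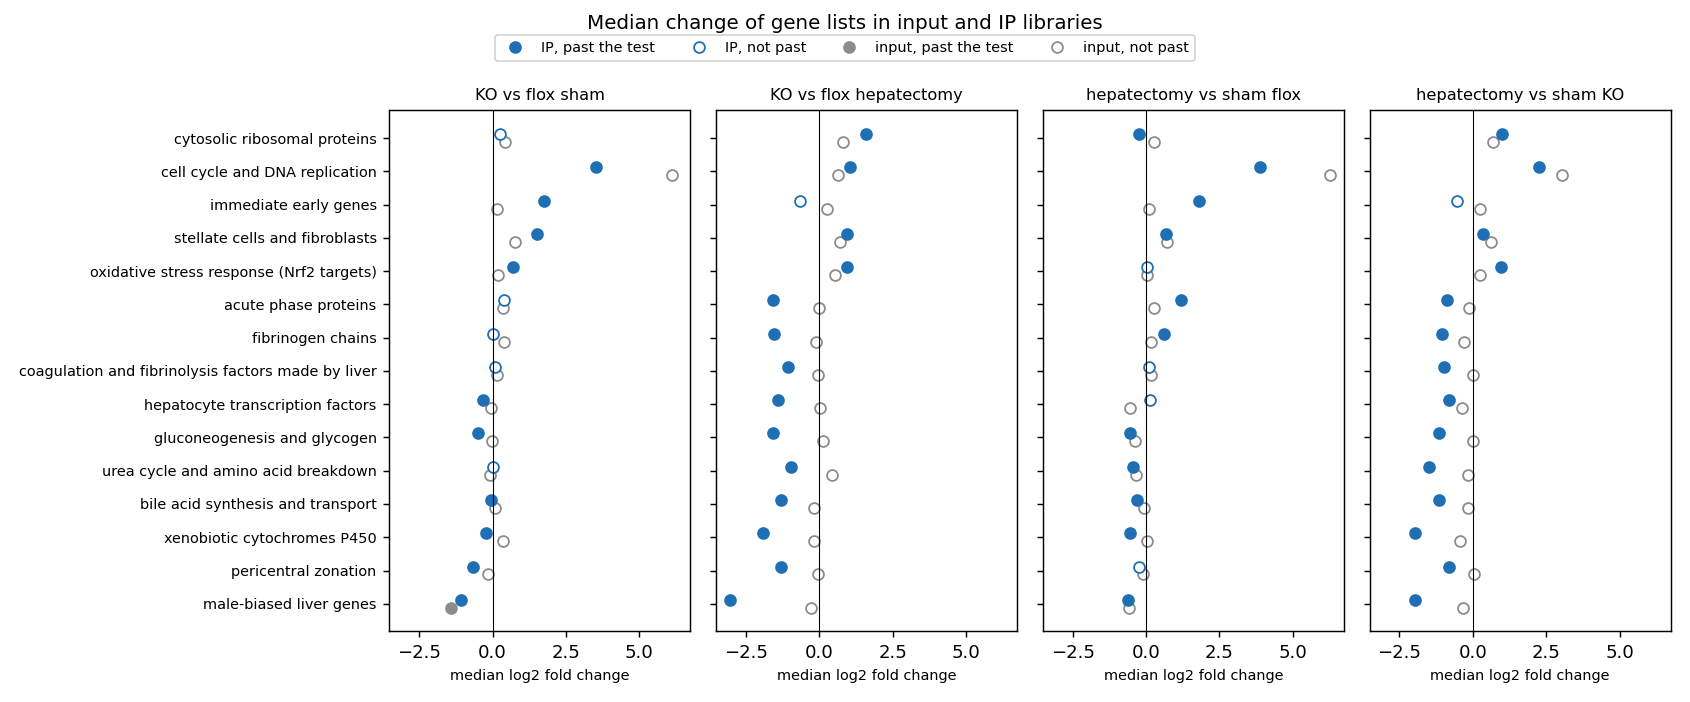
Median log2 fold change of gene lists in 4 comparisons, inputs in grey and IP libraries in blue, filled where the list passed at the preset correlation. After hepatectomy in KO against flox animals the IP medians of ribosomal protein and acute phase genes lie at 1.59 and -1.59.

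Whether mRNAs called enriched in the IP libraries of control livers changed in abundance in KO livers was asked with sets and inputs from different animals. The 33 genes enriched in sham flox animals had a median log2 change of 0.01 between KO and flox inputs after hepatectomy (p = 0.89, p = 0.91 with an estimated correlation). The median gene was at 0.46 there. Of the 174 genes enriched in hepatectomised flox animals 166 were tested in the sham inputs, with a median of 0.39 (p = 0.07, p = 0.34 with an estimated correlation), where the median gene was at 0.29. Most of the 174 were not called enriched with the 50 CPM filter, which gave 11. The median of the first set was -0.54, -0.14 and -0.12 without hepatectomised KO replicates 3 and 4 and flox replicate 4. The second set was at 0.49 and 0.41 without sham KO replicates 2 and 3 and at 0.9 without sham flox replicate 3. The p of the second set in these 3 fits was 0.015, 0.043 and 0.012. Of the second set 55 genes were also lower in IP/input of hepatectomised KO than flox animals, with a median of 0.69 in the sham inputs (p = 0.27, p = 0.43 with an estimated correlation).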

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

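The splits of the libraries and the comparison of ribosomal protein genes with matched genes were planned before their results were seen; all other tests of explanations here were chosen after the result was seen, and so were the comparisons within the IP libraries.

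In 11 of 110 groups of 4 libraries 1 library lay far from the other 3, where chance gives about 1 in 20. The input library of hepatectomised KO replicate 2 had a total count of 10566456, against 12214838 to 12533931 in the others. The IP library of sham KO replicate 4 had 16829 genes with at least 10 counts (others 10999 to 11811). The 10 most abundant genes took 19.5% of the counts of the input library of sham flox replicate 1 (others 21.3 to 21.6%). Fga stood at 52600 CPM in the IP library of sham flox replicate 3 (others 21400 to 23300), Fgb at 16600 CPM in the input library of sham KO replicate 2 (others 11800 to 12400). Trf stood at 15100 CPM in the input library of hepatectomised KO replicate 4 (others 12700 to 12800) and mt-Co1 at 12300 CPM in the input library of sham flox replicate 1 (others 7550 to 7970). In IP libraries Hsd3b5 stood at 452 CPM in sham flox replicate 1 (others 203 to 245), at 1.03 CPM in sham KO replicate 3 (others 0 to 0.0757) and at 219 CPM in hepatectomised flox replicate 4 (others 23.8 to 40.4). Cyp8b1 stood at 3.29 CPM in hepatectomised KO replicate 2 (others 0 to 0.0549).

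The response to surgery differed between genotypes for 6 genes in IP/input by the interaction test, among them Nifk (-17.89), Sdf4 (-14.89), Metap2 (-14.72), Commd1 (26.25) and Serpina1e (-3.42). Of 100 groupings of the same animals, the real one included, 49 gave as many genes and 1 gave 742, so chance was not excluded for this count. Why a grouping called so many was not tested. In IP the interaction passed for 4 genes, Cyp8b1 (-8.11), Gm8893 (-4.12), Slc3a1 (-5.54) and Elovl3 (-9.28), against at most 3 in the other groupings. Without the 2 animals aged 77 days 2 genes passed. Such groupings mix all 4 groups. They also break up the effects of genotype (210 genes after hepatectomy) and surgery (89 in KO animals), so they cannot exclude chance for an interaction.

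Group differences were smaller in input than in IP libraries. Over 498 genes with a mean of at least 200 CPM the slope of input on IP log2 changes was 0.26 in sham and 0.25 in hepatectomised KO against flox animals, and 0.2 and 0.21 for surgery in flox and KO animals (highest 0.26, 95% interval over resampled genes 0.15 to 0.37). This argues against few distinct molecules in the inputs as the whole cause, since noise alone leaves a slope of 1. Transcripts shared between input libraries may be a cause: 12 pairs of gene and comparison (10 distinct genes) almost lacking in the IP libraries of a group stood in its inputs at a median of 45.9% of the other group, from 0.155% (Ly6d) to 182% (Dio1). This test first took genes under 1 CPM in all lacking libraries (2 genes, median 89.9%) and was loosened after those values were seen. Of the 12, 10 compare genotypes, where lost methylation predicts the same, and the 2 within a genotype stood at 44.8% and 52.2%, so both explanations stay open. Selection of changed methylation by the antibody predicts a higher slope for surgery in animals without the enzyme, and the slope in KO animals was higher by 0.02 only. This counts against it if the KO animals lack the enzyme, which could not be read from Mettl14 (0 counts in 16 of 16 inputs), so it stays open.

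Ribosomal protein mRNAs were higher in the IP libraries of hepatectomised KO animals. They exceeded 448 genes matched on deposited gene length and abundance by 1.81 (95% interval 1.65 to 2.16). The interval is over resampled genes, which are not independent replicates. Between animals the mean log2 level of the list ran from 6.12 to 7.89 in KO and from 5.27 to 5.81 in flox. The excess over matched genes argues against gene length and abundance as the cause, while the length of the transcripts was not matched. Loss of the methyltransferase alone would act in both surgeries: the difference was 0.42 in sham animals (exact permutation p = 0.17) and 1.55 after hepatectomy (exact permutation p = 0.029), which leaves this open. Fewer hepatocytes in the samples could raise the markers of every other cell type alike. Over members with a mean of at least 5 CPM, medians were 0.96 for stellate cells (Col1a2 113 to 238 CPM), 0.41 for endothelium (Fcgr2b 224 to 349 CPM), 0.58 for macrophages (Clec4f 232 to 340 CPM) and 0.76 for cholangiocytes (Sox9 48.4 to 82 CPM), a spread of 0.55. The cholangiocyte value rests on 3 members, and all 8 tested gave 0.21. A loss of hepatocytes alone would raise ribosomal protein mRNAs no more than such markers. Their median was 1.59, above each of these resident lists (highest upper 95% limit, over genes, 1.12). This comparison was made after the values were seen, and not every other cell type lay below 1.59. Fewer hepatocytes therefore stays open as a cause. With erythroid genes (median -0.69) included, as first tested, the spread was 1.65, and the restriction to resident types was made after that value was seen. Monocyte and neutrophil markers stood at 1.92, above the ribosomal protein genes, but had only 2 members at 5 CPM, so neither version used them.

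Acute phase mRNAs had 2 levels among the sham flox IP libraries: mean log2 levels were 6.38 and 7.13 in the 2 animals aged 77 days and 8.7 and 8.67 in the younger 2. The difference of 1.93 may come from age, but with 2 animals each and no other animals of that age this stays open. Hepatectomised animals among those named sham are argued against by the cell cycle genes, whose highest log2 level in the 2 high libraries was 1.82, below the lowest hepatectomised flox library at 2.48. No biological explanation other than age was tested.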

How the results depend on the processing

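The 50 CPM filter, the fits without the animals aged 77 days and all results of IP libraries alone were added after the data had been seen. Of 4268 values of 282 gene results under the alternatives, 3471 kept their direction and their side of the threshold, 585 lost and 175 gained a call and 37 turned direction. Causes were not tested, except that fits of fewer libraries or genes hold less information. Counts follow in the order KO against flox sham, KO against flox after hepatectomy, hepatectomy against sham in flox, the same in KO, and interaction, where they moved by over 1.5 times. DESeq2 gave 653, 1052, 1353, 148 and 1240 genes in input, 2483, 3231, 3349, 1611 and 3190 in IP/input. They were 186, 809, 274, 414 and 268 in IP, and 3537, 4127, 2075 and 2040 for IP over input in sham flox, hepatectomised flox, sham KO and hepatectomised KO animals. Without the filter on low counts they were 11, 5, 1, 5 and 3 in input. They were 31 (sham), 74 (flox), 16 (KO) and 54 (interaction) in IP/input, 65, 430, 71, 278 and 81 in IP, and 103 in sham flox and 11 in sham KO for IP over input. With the 50 CPM filter they were 0 (sham), 0 (hepatectomy) and 0 (KO) in input (edgeR; 804, 1227 and 242 at an unadjusted p under 0.05 with the usual filter). They were 27 (hepatectomy) and 13 (flox) in IP/input, 377 (hepatectomy), 2 (flox) and 228 (KO) in IP, and 20, 11, 5 and 77 for IP over input. Without the animals aged 77 days they were 11 (sham), 1 (flox) and 4 (interaction) in input, 3 (flox) in IP/input, 8 (sham), 0 (flox) and 2 (interaction) in IP and 12 for IP over input in sham flox. With age as a covariate they were 3 (sham) and 2 (KO) in input and 8 (sham) and 0 (flox) in IP. A log2 change of at least 1 left 0 (sham) and 1 (hepatectomy) in input, and a log2 of at least 2 left 25 in hepatectomised KO for IP over input. Upper-quartile factors gave 0 (input, sham). Library totals gave 1 (sham), 37 (hepatectomy) and 17 (flox) in IP/input and 85 in hepatectomised flox for IP over input, and TMM within each kind of library 5 in sham KO. Only the 8 libraries compared gave 1 (input, hepatectomy) and 126 (hepatectomy), 1 (flox) and 9 (KO) in IP. The replicate number, which pairs nothing in the labels, gave as a block 17 (sham), 2 (flox), 5 (KO) and 5 (interaction) in input. The animal as a block gave 69 in hepatectomised flox and 16 in sham KO for IP over input, and 12, 48, 5, 25 and 15 in IP/input; it changed no other call than those named with the comparisons. List tests passed 151 times at the preset correlation, 36 times with an estimated one and 164 times by fry, which called other lists in part.

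Leaving out 1 library or animal gave 2 to 17, 3 to 9, 0 to 5, 2 to 9 and 1 to 4 genes in input, 1 to 6, 21 to 70, 8 to 30, 2 to 14 and 1 to 35 in IP/input. It gave 7 to 19, 116 to 457, 0 to 8, 35 to 253 and 3 to 39 in IP, and 9 to 26, 57 to 82, 2 to 7 and 20 to 51 for IP over input. The median of genes enriched in sham flox animals went from -0.54 to 0.41 and that of genes enriched in hepatectomised flox animals from 0.36 to 0.9.

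Most values that turned direction were small; Aurka, at 6.9 with all libraries, and the median of genes enriched in sham flox animals moved far. Fgb in IP over input of hepatectomised flox was -0.19 with DESeq2, -0.18 with library totals, -0.02 without the low-count filter and -0.04 with the 50 CPM filter, and Fgg -0.38, -0.37, -0.21 and -0.22, -0.11 with TMM within each kind of library, -0.06 with the animal as a block and from -0.23 to 0.19 without 1 animal. In IP/input of sham animals Fga was 0.1 with DESeq2, 0.13 with library totals and from -0.44 to 0.04 without 1 animal, and Fgb 0.07 and 0.1 with DESeq2 and library totals. In IP of sham animals Fga was -0.01 with upper-quartile factors, -0.14 with age, -0.31 without the animals aged 77 days and from -0.16 to 0.44 without 1 library. Fgb was -0.19 without the animals aged 77 days and -0.21 without sham KO replicate 2; Fgg was 0.01 with the 50 CPM filter and from -0.41 to 0.2 without 1 library, and Aurka from 0 to 7.33. In hepatectomised inputs Fga went from -0.25 to 0.02 without 1 library, and without KO replicate 2 Fgb was 0.13 and Fgg 0.05. The medians of genes enriched in sham flox animals of -0.54, -0.14 and -0.12 came without hepatectomised KO replicates 3 and 4 and flox replicate 4. The set of genes enriched and lower in KO was not run for genes enriched in sham flox animals, since it held 2 genes; for those enriched in hepatectomised flox animals it held 55 (median 0.69). In simulated data with the spread of these libraries edgeR recovered 4% of 16-fold changes in input, 42% in IP and 2% in IP/input, and at a low spread 100% in all 3.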

Other observations

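A few clock genes and genes of fatty acid oxidation and complement were also lower in the IP libraries of hepatectomised KO animals, while their lists did not pass with an estimated correlation. These genes were chosen after their values were seen, and their calls were not recomputed with libraries left out. Dbp, a transcription factor driven by the circadian clock, stood at 104 ± 87.3 CPM in flox and 9.11 ± 2.6 in KO animals (log2 change -3.51, SE 0.73, adjusted p = 0.0096, n = 4 each). Its partner Tef was at -2.9 (SE 0.72, adjusted p = 0.036). Of 13 clock genes 2 fell, 2 adjusted over the list alone (median -0.99, adjusted p = 0.0053, adjusted p = 0.13 with an estimated correlation). Of 18 genes of fatty acid oxidation 3 fell, 5 adjusted over the list alone (median -0.34, adjusted p = 0.0084, adjusted p = 0.29 with an estimated correlation). Of 21 complement genes 3 fell, 6 adjusted over the list alone (median -0.59, adjusted p = 0.00071, adjusted p = 0.18 with an estimated correlation), among them C1ra (-1.24) and C1s1 (-1.68). From sham to hepatectomised KO animals 5 of 13 periportal genes fell, 9 adjusted over the list alone (median -1.49, adjusted p = 2.5e-07, adjusted p = 0.049 with an estimated correlation), with Gls2, a glutaminase, at -2.55 and Cyp2f2 at -2.27.

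Other splits of the same libraries, planned for each comparison, tested whether chance alone gives as many genes. Chance was not excluded for the input counts of edgeR: 1 against at most 4 in other splits for KO against flox sham, 3 against 5 after hepatectomy, 0 against 3 and 1 against 6 for hepatectomy in flox and KO animals, and 0 against 8 for the interaction, where 100 of 100 splits gave as many. With DESeq2 the real split of KO against flox after hepatectomy gave 1052 genes against at most 808, the highest of 25 splits. In sham animals 5 of 25 gave as many as the real one. The outcome for KO against flox inputs after hepatectomy thus depended on the tool. For IP over input the 2 libraries of an animal are a pair, and only 8 splits part every pair as the real one does, too few for a share under 0.05. Counts were 37 against at most 1, 174 against 0, 3 against 1 and 47 against 1 in sham flox, hepatectomised flox, sham KO and hepatectomised KO animals. In the 27 splits that keep both libraries of some animals together the highest was 19, in hepatectomised KO animals. In IP/input only the real split reached its count for KO against flox after hepatectomy (102 against 5). Chance was not excluded for sham animals (3 against 3), flox (26 against 36) or KO animals (5 against 7). In IP only the real split reached its count for KO against flox in sham (13 against 1) and hepatectomised animals (210 against 1). The same was so for hepatectomy in flox (4 against 0) and KO animals (89 against 18). To be alone among 35 splits is the smallest share possible, and it was not adjusted over the comparisons. The 4 genes in flox animals went to 0 with age as a covariate or without the animals aged 77 days. Chance was thus not excluded for them. For the genes enriched in flox animals chance was not excluded either. In an exact permutation over 35 splits, with the camera p as the statistic, 4 and 27 splits gave a value as small as the real p = 0.07 and 0.89, the smallest elsewhere being 0.025 and 0.001.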
